A study of Taeniopygia guttata with 40 samples.

How the data were processed

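The data were reduced representation bisulfite sequencing libraries from whole brains of 40 zebra finch (Taeniopygia guttata) embryos. In this assay genomic DNA is digested with restriction enzymes, here MspI and TaqI, so that short fragments rich in CpG dinucleotides are sequenced. Bisulfite treatment then turns unmethylated cytosines into uracil, which is read as T, while methylated cytosines are read as C. Per the labels' protocols, each library was made from 300 ng of DNA with 9 PCR cycles, fragments near 250 bp were selected, and reads were 50 bp long from a single end. No molecular identifiers were described, so reads copied from the same molecule could not be told from independent molecules, and intervals and limits taken from reads cover counting error only.

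The deposited tables hold, per the file headers, 1 line for each strand of each CpG, with counts of reads that kept a C, counts of reads that showed C or T, counts of opposite-strand reads that showed G, and counts of opposite-strand reads that showed G or A. The deposited ratio is a fraction from 0 to 1 per the file headers. The headers also name an effective count of C or T reads. The ratio was recomputed, to within 0.00462 in every library, as C reads over that effective count, capped at 1. Methylation was calculated here from the plain counts of C or T reads, so it need not equal the deposited ratio. Neither that ratio nor the effective count was used further. The submitters' processing notes name Trim Galore 0.4.1, FastQC 0.11.5 and SAMtools. The build is bTaeGut1.4.pri per the series' design text, and the aligner and the methylation caller are not given in the sources used here. Only CpG sites are in the tables used here, so non-CpG methylation was not analysed here. Sequences are named as in the tables. The Z chromosome is NC_044241.2, the W chromosome is NC_045028.1 and the mitochondrial genome is NC_007897.1, and all coordinates are 1-based.

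Groups were taken from the labels. There were 6 control call female, 14 control call male, 8 heat call female and 7 heat call male embryos, 35 in all, and 5 further heat call female libraries that the labels mark as excluded for quality. The reason the labels give is an anomalous bisulfite conversion profile, low CpG coverage, or both, without saying which applies to each library. The labels give no clutch and no batch, so neither could be a term in a model. The series' design text describes a treatment assignment balanced within clutches. Each library is a separate embryo. Because the sex chromosome reads did not follow the labelled sex (see the first comparison), the sexes are called labelled female and labelled male.

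Counts of both strands of a CpG were summed. A count was usable if it held at least 10 reads and did not exceed the 99.9th percentile of its library. A CpG was tested if at least 5 embryos in each of the 4 retained groups had a usable count and its pooled methylation lay between 2% and 98%. The W chromosome was left out of these tests. Non-overlapping windows of 500 bp were tested if they held at least 3 tested CpGs, with reads summed per embryo.

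Each CpG and window was tested with a quasi-binomial logistic model of methylated and unmethylated counts over the 35 retained embryos, with treatment and labelled sex as terms. The overdispersion came from the Pearson residuals and was not allowed below 1, the term was tested with an F test, and Benjamini-Hochberg adjustment ran over all features tested. Differences are model-adjusted and in percentage points. A feature was called at an adjusted p under 0.05 with a difference of at least 10 points for CpGs and at least 5 points for windows. The interaction was tested by adding a treatment by labelled sex term. The models were fitted in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. limma 3.58.1 in R 4.3.3, on the log2 ratio of methylated to unmethylated reads with 1 read added to each, was the other tool.

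The fit was tested on simulated data. Counts were drawn for the 317615 tested CpGs with the real depths and with the overdispersion that a fit to the deposited counts gave, and 50 CpGs of each size were changed. For treatment the model called 0, 7, 22 and 45 of the 50 CpGs changed by 10, 20, 30 and 40 points, beside 30 false calls. For labelled sex it called 1, 10, 22 and 35, beside 48 false calls, and for the interaction 0, 0, 2 and 6, beside 3 false calls. Over the 41055 windows it called 0, 13, 21 and 33 of the 50 windows changed by 5, 10, 15 and 20 points, beside 22 false calls. The changed CpGs and windows were drawn only from those of intermediate pooled methylation. The shares recovered therefore need not hold for CpGs or windows of low or high methylation. False calls were counted over unchanged features of all levels and were not separated by level. In the treatment simulation 9.40% of unchanged CpGs had an unadjusted p under 0.05, so the p-values of this model ran low there. In the deposited counts 7.18% of all tested CpGs did, so the amount in the simulation need not hold for these data.

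Methylation of an embryo was its mean over the 158521 autosomal CpGs with at least 10 reads in every retained embryo, and over subsets by CpG density, methylation level and chromosome. These means were compared with a two-sided permutation test of the treatment coefficient, adjusted for labelled sex, with treatment permuted within labelled sex in 100000 resamples, and adjusted over the family of 11 measures. The 5 excluded libraries were compared with the 8 retained heat call female libraries with a two-sided exact permutation test over all 1287 splits, adjusted over 12 measures. Reads from the strand opposite to a cytosine show a true C-to-T variant as A. Autosomal sites with both alleles common in those reads served as 1296 variant sites for genotypes and for relatedness between embryos.

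The regions named in the text followed a rule fixed beforehand: the called 500 bp windows of largest difference, up to 8 in each direction, filled up by the windows of lowest p where fewer were called and then given as values that did not pass, with the 5 autosomal and 5 Z windows of lowest p for labelled sex and the 5 windows of lowest p for the interaction. All called CpGs that are named, and the windows named for their spread between embryos, lie outside this rule and were chosen after their values were seen. The groups, the tests, the thresholds, this rule and a list of other settings to try were set before the data were examined. Those settings changed the read minimum, the filters, the covariates, the embryos, the windows and the tool, and others were chosen after seeing the data. Tests of promoters, gene bodies, gene lists and cell type markers had been planned as well. They need an annotation of the build used in the tables and were not run, so no gene is named and those features were not analysed here.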

Results

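Zebra finch parents give a particular call in the nest when it is hot, known as a heat call, and embryos hear it before hatching. The study asked whether hearing such calls alters DNA methylation in the embryonic brain. Eggs were kept at 37.5 °C and 60% humidity, and recordings of heat calls or control calls were played at 65 dB for 9 hours on each of embryonic days 10 to 13. Whole brains were taken on embryonic day 14. The retained set comprised 20 control call embryos, 6 labelled female and 14 labelled male, and 15 heat call embryos, 8 labelled female and 7 labelled male. The 5 heat call female libraries excluded by the submitters were compared separately.

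Over the 40 libraries the tables held 2486799 CpGs. The retained libraries held from 22118083 to 124542275 reads over CpGs (median 39385039), and from 747434 to 1668511 CpGs with at least 10 reads. The excluded libraries held from 8579269 to 84589438 reads. Control call females held from 22118083 to 71963640 reads, control call males from 25920180 to 86530509, heat call females from 23425296 to 124542275 and heat call males from 30950335 to 94880660. In the retained libraries the share of mitochondrial CpG reads that kept a C, a guide to incomplete conversion, lay between 0.341% and 0.797%.

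The first comparison set the labelled sex against the reads on the sex chromosomes. Female birds carry a Z and a W chromosome, and males carry a pair of Z chromosomes. The libraries fell on separate levels: 17 libraries had 2.94% to 3.79% of their reads on the W and 2.92% to 3.32% on the Z, and the other 23 had 0.472% to 0.666% on the W and 5.23% to 6.32% on the Z. The labels did not follow these levels. The upper W level held 3 of 6 control call females, 7 of 14 control call males, 4 of 8 heat call females, 3 of 7 heat call males and 0 of 5 excluded heat call females. In 22 of the 40 libraries, and in 17 of the 35 retained ones, the W reads went against the labelled sex (Fisher's exact test of labelled sex against W level, two-sided, p = 0.538 over 40 libraries and p = 1 over the 35 retained). Groups were kept as labelled, and every comparison of labelled sexes below carries this limit.

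**Figure D1:**
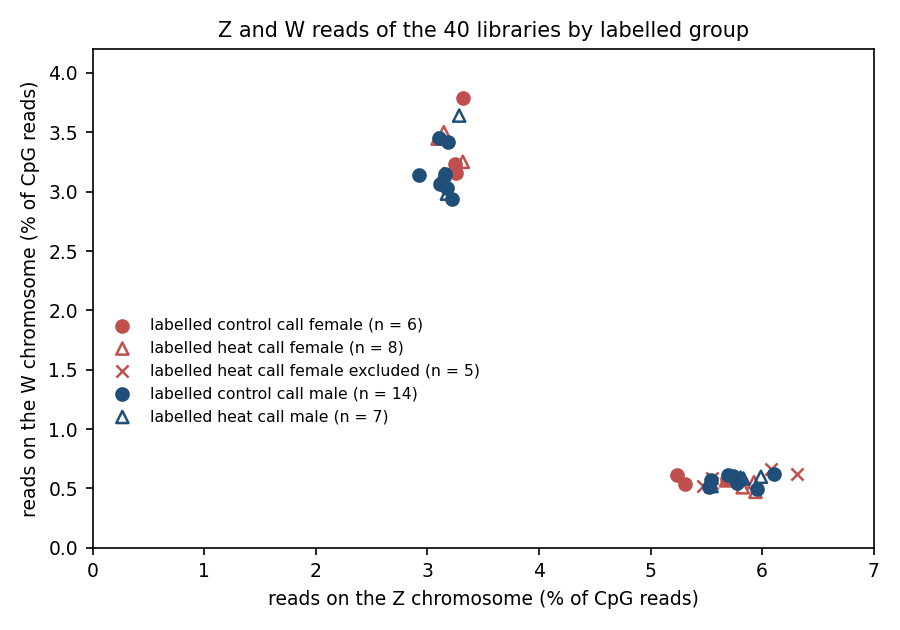
Share of CpG reads on the Z chromosome (horizontal, %) and on the W chromosome (vertical, %), 1 point per library, by labelled treatment and sex. Labelled females and labelled males lie together at both levels of W reads, with no library between 0.666% and 2.94%.

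The second comparison asked whether heat calls shifted methylation across the genome. Autosomal CpGs of the embryonic brain had a mean methylation of 21.1% ± 0.254 (SD, n = 15) after heat calls and 21.2% ± 0.411 (SD, n = 20) after control calls, with 7 of 15 heat call embryos above the control median. CpGs in dense clusters, with at least 10 others within 100 bp, were methylated at 13.9% ± 0.256 (SD, n = 15) and 13.9% ± 0.324 (SD, n = 20). Isolated CpGs, with at most 3 others within 100 bp, were methylated at 44.7% ± 0.465 (SD, n = 15) and 44.6% ± 0.626 (SD, n = 20). Z chromosome CpGs stood at 38.4% ± 0.436 (SD, n = 15) and 38.4% ± 0.505 (SD, n = 20). Of the 158521 autosomal CpGs, 71.8% lay under 20% methylation, 15.5% between 20% and 80%, and 12.8% above 80%.

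The autosomal difference, heat call minus control call, was -0.0706 points (SE 0.126, 95% interval -0.326 to 0.185, permutation p = 0.584, adjusted p = 0.902). Without control call female replicate 46 it was 0.00375 points. The lowest p of the 11 measures belonged to mitochondrial reads that kept a C, at 0.520% ± 0.107 (SD, n = 15) against 0.581% ± 0.124 (SD, n = 20) (difference -0.0804 points, permutation p = 0.0472, adjusted p = 0.520). By labelled sex, autosomal methylation was 21.2% ± 0.410 (SD, n = 14) in females and 21.2% ± 0.311 (SD, n = 21) in males (permutation p = 0.597, adjusted p = 0.725).

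**Figure D2:**
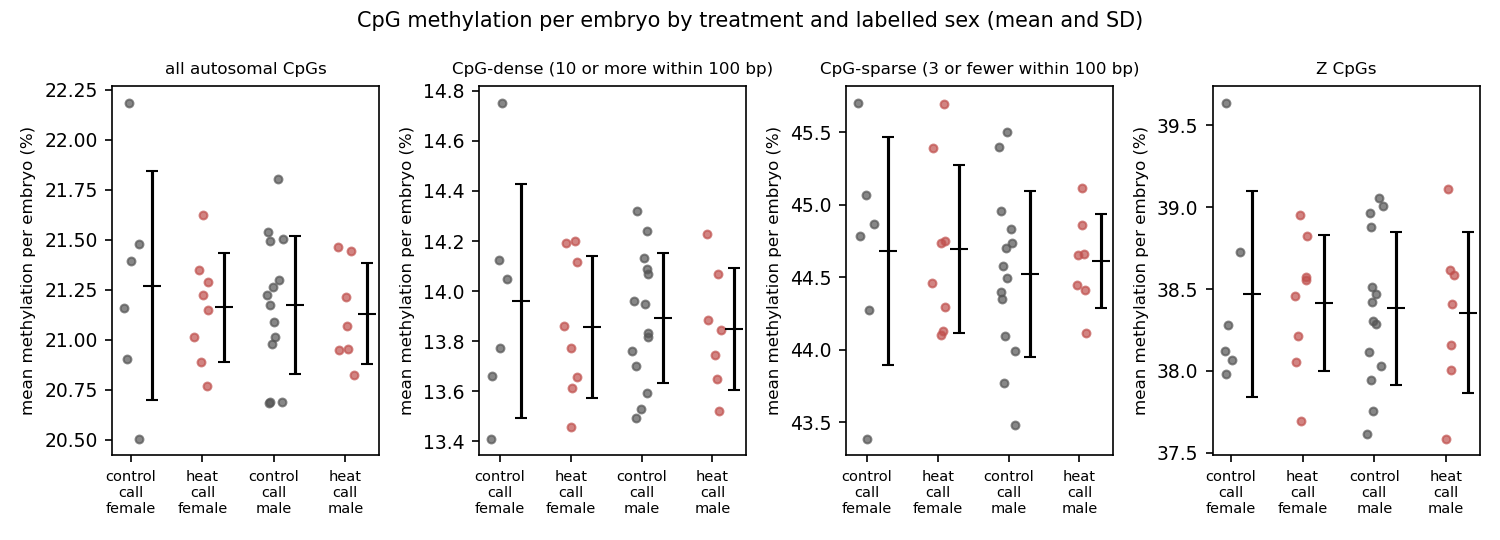
Mean CpG methylation per embryo (%) over 4 sets of CpGs, by treatment and labelled sex. Points are embryos, and the bars beside them give the mean and SD of each group, which overlap in every set.

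The third comparison looked for regions that differed between heat call and control call embryos. Of the 41055 windows of 500 bp tested, the one of lowest p was NC_044212.2 from 635501 to 636000, with 6 tested CpGs, 1 of them with variant reads, at 45.8% ± 12.7 (SD, n = 15) after heat calls and 28.9% ± 7.87 (SD, n = 18) after control calls. All 15 of those heat call embryos lay above the control median. The window at NC_044217.2 from 31549001 to 31549500 stood at 71.1% ± 11.2 (SD, n = 14) and 45.98% ± 18.6 (SD, n = 14). In the other direction, the window at NC_044214.2 from 96423001 to 96423500 stood at 11.1% ± 6.14 (SD, n = 15) after heat calls and 23.6% ± 10.3 (SD, n = 18) after control calls, with 15 of 15 heat call embryos below the control median. The Z window from 41740501 to 41741000, with 8 tested CpGs, stood at 58.8% ± 11.9 (SD, n = 15) and 68.2% ± 10.0 (SD, n = 20).

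None of these values passed the test. The quasi-binomial model called 0 of 41055 windows, with 2514 at an unadjusted p under 0.05 and a lowest adjusted p of 0.602, and limma called 0, with 1514 at an unadjusted p under 0.05. The fitted differences of the 4 windows above, heat call minus control call, were 13.7 points (SE 2.78), 23.7 points (SE 5.27), -11.7 points (SE 2.53) and -13.0 points (SE 2.77). Over the 8 windows of lowest p in each direction the fitted differences ranged from 5.12 to 23.7 points and from -20.1 to -3.72 points. The median number of reads per embryo behind these 16 windows ran from 82 to 341. The model's 95% interval lay within 10 points on either side of 0 in 77.2% of windows and within 20 points in 98.5%, and within 5 points in 33.3%. In simulated data 9.22% of unchanged windows had an unadjusted p under 0.05, and in the deposited counts 6.12% of all tested windows did. These intervals are therefore too narrow to exclude changes of those sizes at the 95% level, by an amount not settled here.

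**Figure D3:**
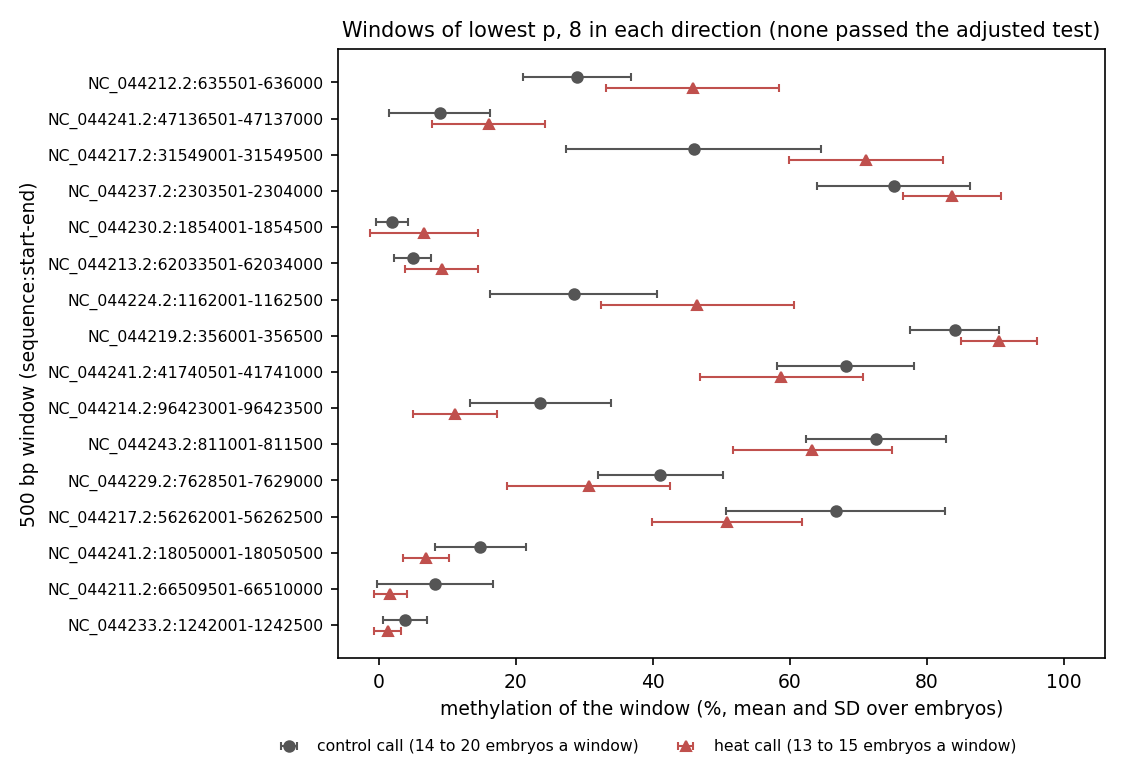
Methylation (%, mean and SD over embryos) of the 8 windows of lowest p in each direction, for control call embryos (grey circles) and heat call embryos (red triangles). The means differ in each window while the SD bars overlap in each, and no window passed the adjusted test.

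At single CpGs, 13 of 317615 passed the test between heat call and control call embryos, 9 higher and 4 lower after heat calls, all of them on autosomes. The first 4 examples were chosen after their values were seen and have the largest differences of the 13. The CpG at NC_054766.1 position 120515 stood at 90.6% ± 7.84 (SD, n = 15) after heat calls and 69.2% ± 12.2 (SD, n = 20) after control calls (19.5 points, adjusted p = 0.0362, 15 of 15 heat call embryos above the control median). The CpG at NC_044238.2 position 4697547 stood at 99.4% ± 1.72 (SD, n = 14) and 81.4% ± 17.96 (SD, n = 15) (21.1 points, adjusted p = 0.0145, 14 of 14 above). The CpG at NC_044222.2 position 19852350 stood at 48.7% ± 15.2 (SD, n = 14) and 76.5% ± 13.6 (SD, n = 16) (-30.1 points, adjusted p = 0.0348, 13 of 14 below). The CpG at NC_044212.2 position 28556680 stood at 76.9% ± 19.1 (SD, n = 13) and 99.4% ± 1.71 (SD, n = 15) (-25.6 points, adjusted p = 0.0145, 10 of 13 below).

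The median depth of the 13 CpGs ran from 17 to 35 reads per embryo. The adjusted p-values came from the quasi-binomial model, which had 22801 CpGs at an unadjusted p under 0.05. limma called 0 CpGs, with 13862 at an unadjusted p under 0.05, and the quasi-binomial model called 0 with a minimum of 20 reads, a filter under which only 1 of the 13 was still tested. In 7 of the 13 at least 1 of the 4 groups had no methylated or no unmethylated read, against 6.23% of tested CpGs at the same pooled methylation. Here and in the comparisons below, these tested CpGs were not matched on the size of the difference. Without the 17 retained libraries whose W reads went against their labels, which left 18 embryos, the quasi-binomial model also called 0. Other settings called more, 90 CpGs with a minimum of 5 reads, 57 without the filter on pooled methylation, 41 with the log of reads as a covariate and 481 with 3 genotype axes.

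The fourth comparison set labelled females against labelled males. At 24 CpGs, 23 autosomal and 1 on the Z, methylation differed, 13 higher and 11 lower in labelled females. The count was 143 with a minimum of 5 reads, 1 with a minimum of 20 reads, and from 19 to 54 when single embryos were left out. Without the 17 libraries at odds with their labels it was 52, of which 2 were among the 24. The CpG at NC_054765.1 position 1107973 stood at 89.5% ± 9.27 (SD, n = 11) in labelled females and 62.6% ± 14.7 (SD, n = 15) in labelled males (27.9 points, adjusted p = 0.0176 in the quasi-binomial model), and the CpG at NC_044217.2 position 36917752 at 20.1% ± 15.6 (SD, n = 13) and 43.6% ± 16.8 (SD, n = 19) (-28.4 points, adjusted p = 0.0101). Both were chosen after their values were seen. Of the 24 CpGs, 10 had a group with no methylated or no unmethylated read, against 6.13% of tested CpGs at the same pooled methylation. The autosomal window of lowest p, NC_044223.2 from 11277501 to 11278000, stood at 41.9% ± 9.40 (SD, n = 14) and 29.98% ± 9.09 (SD, n = 21). The Z window of lowest p, from 66016001 to 66016500, stood at 93.0% ± 4.40 (SD, n = 13) and 97.6% ± 2.65 (SD, n = 20). Neither window passed the quasi-binomial test, which called 0 of 41055 windows for labelled sex with 2900 at an unadjusted p under 0.05. limma called 0 CpGs, with 15358 at an unadjusted p under 0.05. The upper W level held 7 of these 14 labelled females and 10 of these 21 labelled males, and in 17 of the 35 libraries the W reads went against the labelled sex. These are therefore differences between labels, in the direction of the labels, and were not shown to be differences between the sexes.

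The fifth comparison asked whether the treatment difference itself depended on labelled sex. The interaction term passed at 40 CpGs, 9 with a treatment difference higher in labelled females and 31 with one lower. At NC_044217.2 position 49626522, chosen after its values were seen, labelled females stood at 0% after heat calls (n = 7, no methylated read in 193, which allows up to 1.55%) and 12.6% ± 9.94 (SD, n = 5) after control calls, while labelled males stood at 6.43% ± 5.85 (SD, n = 5) and 0.334% ± 1.21 (SD, n = 13). In 33 of the 40 CpGs at least 1 of the 4 groups had no methylated or no unmethylated read, against 22.5% of tested CpGs at the same pooled methylation. The window of lowest p, NC_044220.2 from 2047001 to 2047500, stood in labelled females at 10.5% ± 8.46 (SD, n = 6) after heat calls and 0.673% ± 0.881 (SD, n = 6) after control calls, and in labelled males at 2.52% ± 2.40 (SD, n = 7) and 3.15% ± 2.44 (SD, n = 14), and did not pass. No window passed in the quasi-binomial model (0 of 41055, 2294 at an unadjusted p under 0.05). limma called 0 CpGs for the interaction, with 12831 at an unadjusted p under 0.05, and without heat call female replicate 41, the deepest library, the quasi-binomial model called 0.

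The last comparison set the 5 excluded heat call female libraries beside the 8 retained ones. Their mean autosomal methylation was 22.3% ± 2.02 (SD, n = 5) and 21.9% ± 1.01 (SD, n = 8), a difference of 0.407 points (exact permutation p = 0.674, adjusted p = 0.808), which was -0.447 points without excluded replicate 51. They held fewer CpGs with any read, 1168552 ± 444071 (SD, n = 5) against 1788655 ± 149888 (SD, n = 8) (exact permutation p = 0.00155, adjusted p = 0.00466, 4 of 5 below every retained library), although their CpG reads were similar, at 45965075 against 45431546 on average (exact permutation p = 0.987). At variant sites they showed fewer heterozygous calls, 11.0% ± 4.66 (SD, n = 5) against 26.003% ± 4.29 (SD, n = 8) (exact permutation p = 0.000777, adjusted p = 0.00311, 5 of 5 below). Of CpGs with pooled methylation between 30% and 70%, 62.2% ± 14.6 (SD, n = 5) were read as entirely methylated or entirely unmethylated in the excluded libraries against 12.9% ± 7.54 (SD, n = 8) in the retained ones (exact permutation p = 0.000777, adjusted p = 0.00311, 5 of 5 above). The smallest p that these 1287 splits can give is 0.000777. The share of mitochondrial reads that kept a C was 0.559% ± 0.135 (SD, n = 5) and 0.558% ± 0.0907 (SD, n = 8) (exact permutation p = 0.990).

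**Figure D4:**
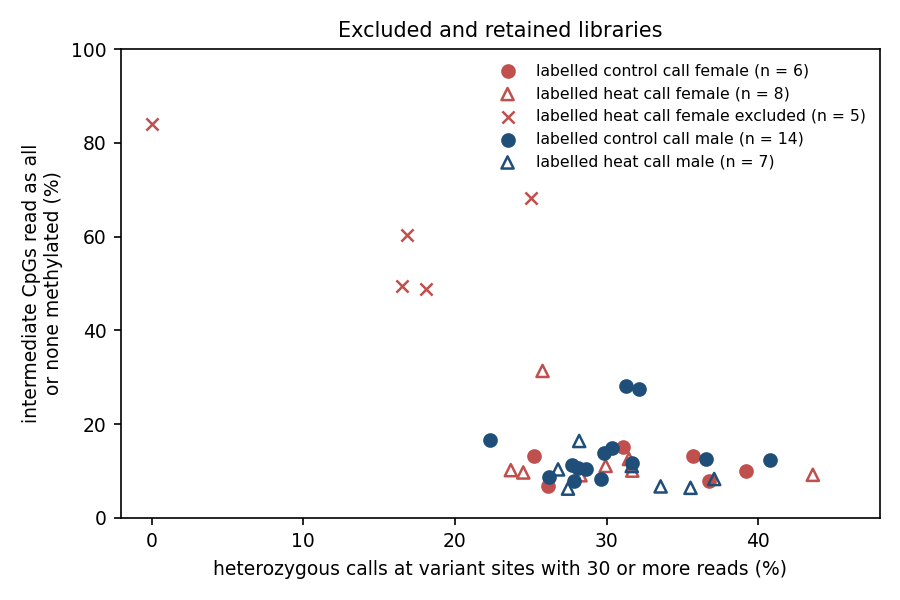
Share of heterozygous calls at variant sites with at least 30 reads (horizontal, %) and share of intermediate CpGs read as all or none methylated (vertical, %), 1 point per library. The 5 excluded libraries lie between 48.8% and 84.0% on the vertical axis, above all 35 retained libraries, whose highest value is 31.4%.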

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

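The tests of mixed DNA, of sex labels unrelated to the libraries, of C-to-T variants at the called CpGs and of groups with no methylated read were chosen only after the result was seen, as were the models with genotype axes and those without the libraries at odds with their labels.

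The labelled sex of 22 of the 40 libraries went against their W chromosome reads, a signal in reads that the methylation comparisons leave out. Mixing of DNA from both sexes is argued against, since 0 libraries lay in the middle 0.5 of the span between the levels of W reads. A constant shift of the library order is argued against too, since the best cyclic shift of the labels brought only 26 of 40 libraries into agreement. Sex labels that are unrelated to the libraries they are attached to remain a candidate explanation, with 18 of 40 libraries in agreement and a Fisher's exact test p of 0.538. The condition and sex entries deposited with the counts matched the label of each library, so they give no sign of labels exchanged after those entries were made. Whether only the sex label or the whole label of a library is affected was not testable in these tables. If the whole label is, the treatment comparison may be mixed as well. No biological explanation was tested.

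The 13 CpGs called between heat call and control call embryos were not more than other splits of the embryos gave: 86 of 100 splits within labelled sex gave as many, the real one included, and the highest other split gave 61, so chance cannot be excluded, and in simulated data the same model made 30 false calls. The labels give no clutch, so these splits and those below could not keep the balance within clutches that the design text describes. A change of the region around each CpG is argued against, since 78 tested CpGs within 200 bp of 12 of them differed by a median of 1.01 points in the same direction (quartiles -0.548 and 3.57), against 12.6 points at the called CpGs. C-to-T variants stay open: opposite-strand reads showed a variant at 1 of the 13, but the bound of few such CpGs was wrong as evidence against them, because only 5 of the 13 had opposite-strand reads in most embryos and 5 had them in none. Adding 3 genotype axes to the model did not remove the differences at the 13 CpGs, which kept their direction at 0.820 to 1.63 times those before. With them 12 of the 13 passed again (the other moved from 10.04 to 9.69 points, under the threshold of 10), while 10 of the 24 CpGs of labelled sex did. That model called 481 CpGs in all, for a reason not tested, so passing again cannot decide the question. Family structure that these axes do not cover stays open. An effect of the heat calls themselves stays open and was not shown by these calls.

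For the 500 bp windows, 82 of 100 splits gave at least the 2514 windows at an unadjusted p under 0.05 (highest other split 3476), and for labelled sex 69 of 100 splits within treatment gave at least the 24 CpGs called (highest other split 123), so chance cannot be excluded for either. Splits that called 61 and 123 CpGs, several times the real counts, may point to a structure of the embryos, which was not tested; the medians of the other splits were 23 and 29, and the model made 30 and 48 false calls in simulated counts without such a structure, so a varying number of false calls stays open as well.

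The treatment difference itself differed between labelled females and labelled males at 40 CpGs, by the interaction term. This count was reached by 4 of 100 splits, the real one included (highest other split 45, median 12, with 3 false calls in simulated data). That is few, but several such counts were compared without adjustment, so chance is not excluded. The 22491 CpGs and 2294 windows at an unadjusted p under 0.05 were reached by 80 and 96 of 100 splits, so chance cannot be excluded for them either. A candidate explanation that stays open is a model run to its edge by groups with no methylated or no unmethylated read, which 33 of the 40 CpGs had, against 22.5% of tested CpGs at the same pooled methylation. Such groups were not special to the interaction, since 7 of the 13 treatment CpGs (against 6.23%) and 10 of the 24 CpGs of labelled sex (against 6.13%) had one too. The tested CpGs were matched on pooled methylation and not on the size of the difference. At low or high pooled methylation a difference of at least 10 points itself pushes a group towards such an edge, so these shares cannot decide the question. The calls also depended on single libraries, with 0 left without heat call female replicate 41 and 3 without control call male replicate 34 or 49, and a sex-dependent response to heat calls stays untested while the sex labels are in doubt.

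In groups of 4 to 10 libraries, 5 of 50 group and measure pairs had a library far from the others, where chance gives about 1 in 20. Heat call female replicate 41 held 124542275 CpG reads, against at most 47432290 in the others of its group. The same library had 43.6% heterozygous calls at variant sites with at least 30 reads, against at most 31.7%. Heat call female replicate 48 read 31.4% of intermediate CpGs as all or none, against at most 12.6%. Heat call female replicate 19 had 91.8% methylation at highly methylated CpGs, against at most 91.2%. Control call female replicate 18 had 71.2% methylation at CpGs of unplaced sequences, against at most 68.6%. The opposite-strand reads, which the methylation comparisons do not use, showed 1296 autosomal variant sites.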

How the results depend on the processing

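The models with W reads, genotype axes, or without libraries at odds with their labels or with many all-or-none CpGs were chosen after seeing the data. Counts below are CpGs called for treatment, labelled sex and the interaction (13, 24 and 40 as reported). With a minimum of 5 reads they were 90, 143 and 93, and with a minimum of 20 reads 0, 1 and 0, where 136304 CpGs were tested in place of 317615 and only 1 of the 13 treatment CpGs was among them (8993, 9421 and 8897 at an unadjusted p under 0.05). Without the filter on pooled methylation treatment gave 57 and labelled sex 214. With the 5 excluded libraries treatment gave 9, of which 4 were among the 13, labelled sex 15, of which 7 were among the 24, and the interaction 136, of which 30 were among the 40. With the log of reads as a covariate they were 41, 51 and 70. With no threshold on the difference treatment gave 78 and labelled sex 126. For treatment, the 14 labelled females alone gave 0 (26460 at an unadjusted p under 0.05), and the 21 labelled males alone gave 10, of which 1 was among the 13. Each strand tested as its own site gave 24, and W reads in place of labelled sex gave 20. With 3 genotype axes they were 481, 194 and 419. Without the 17 libraries at odds with their labels they were 0, 52 and 0 (27998, 30435 and 24303 at an unadjusted p under 0.05), with 18 embryos left. Without the 3 libraries of highest all-or-none share treatment gave 7, all among the 13, labelled sex 33, and the interaction 11, of which 8 were among the 40. limma called 0, 0 and 0 (13862, 15358 and 12831 at an unadjusted p under 0.05). The cause of these changes was not tested.

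Leaving out each embryo in turn, treatment gave 9 to 19 CpGs and labelled sex 19 to 54, above 1.5 times the reported count without control call female replicates 3 (44), 4 (54) and 8 (47) and heat call male replicates 15 (45) and 22 (46). The interaction gave 0 to 55, and fell by over 1.5 times in 21 of 35 cases: without heat call female replicates 5 (14), 19 (10), 24 (11), 29 (6), 31 (25), 41 (0) and 48 (19), heat call male replicates 10 (25) and 35 (24), control call female replicate 46 (24), and control call male replicates 13 (25), 17 (22), 26 (23), 27 (17), 32 (22), 33 (7), 34 (3), 36 (10), 38 (22), 42 (20) and 49 (3). Windows compared by treatment gave 0 under each alternative fitted and in limma, though without the filter on pooled methylation the lowest adjusted p was 0.00176, at a difference under 5 points, and 0 to 1 in leaving out embryos, the 1 being the Z window from 41740501 without control call female replicate 8; window counts for labelled sex and the interaction were not repeated under alternatives. The global difference ranged from -0.12968 to 0.00375 points, reversed only without control call female replicate 46 (0.00375), and from -0.150023 to -0.0199 under the other alternatives, with no p under 0.05. The methylation difference of the excluded libraries ranged from -0.447 to 0.844 points, reversed without excluded replicate 51 (-0.447). Over the settings in which they were tested, the named windows changed call 1 time and direction 0 times, and the 13 CpGs passed 523 times and failed 153 times. Most of these fits only left out 1 embryo from the set on which the CpGs were called, so their passes are not independent support. In the other settings the failures of single CpGs ran from 4 of 17 to 11 of 18. The median standard error of single CpGs was 4.06 points for treatment and 8.30 for the interaction, with a median overdispersion of 5.06 and 4.95. Promoters, gene bodies, gene lists and cell type markers were not run for want of an annotation of the build.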

Other observations

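The relation of methylation to chromosome length and the list of most variable windows were taken up after the data had been looked at, while the bounds for the tests of relatedness, of treatment and of few molecules were set before their results were seen.

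Among CpGs with at least 10 reads in every retained embryo, mean methylation was higher on shorter autosomes. CpG density, with which methylation also varied, was not held constant between chromosomes. Length and the kind of CpG covered on each chromosome therefore cannot be told apart here. CpGs on the 6 autosomes longer than 40 Mb averaged 15.7% ± 0.233 (SD, n = 35), and those on the 26 autosomes shorter than 20 Mb averaged 29.5% ± 0.511 (SD, n = 35). Over the 35 autosomes with at least 500 of these CpGs the mean ran from 14.5% to 72.3%. Its correlation to the log of length was Pearson r -0.825 and Spearman rho -0.925 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). This is a correlation across chromosomes, which are not independent replicates, and r was -0.812 without the 2 autosomes of length farthest from the median. Among these 35 autosomes, the one with the highest mean, NC_054767.1, ended near 2.56 Mb and stood at 72.3% ± 0.912 (SD, n = 35). The longest, NC_044213.2, ended near 152 Mb and stood at 15.1% ± 0.194 (SD, n = 35). The Z, at 38.4% ± 0.470 (SD, n = 35), lay above each autosome longer than 40 Mb, and unplaced sequences stood at 68.5% ± 1.06 (SD, n = 35).

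Some short regions differed far more between embryos than the rest of the genome. Among 7749 autosomal windows with at least 5 CpGs, at least 30 reads in each of the 35 embryos and no variant seen in opposite-strand reads, the median SD between embryos was 5.63 points. The adjoining windows at NC_044236.2 from 145001 to 145500 and from 145501 to 146000, with 11 and 7 CpGs, had SDs of 31.3 and 32.02 points, and single embryos ran from 0% to 98.1% in the second. The window at NC_044214.2 from 76393001 to 76393500, with 11 CpGs and at least 232 reads per embryo, ran from 3.78% to 94.7% around a mean of 51.9% ± 29.7 (SD, n = 35), and the window at NC_044211.2 from 19244001 to 19244500, with 13 CpGs, from 11.1% to 94.96%. Inherited differences are a candidate explanation, yet only 2 of the 8 most variable windows were more alike in pairs of embryos with more similar genotypes (permutation p of 8 windows adjusted together), those on NC_044236.2, with r of 0.136 and 0.145. The other 6 stay open, and variants in the CpGs themselves are not excluded, since opposite-strand reads were present in most embryos at only 1 of the 7 and 6 of the 11 CpGs of the windows on NC_044236.2 and at 7 of the 11 on NC_044214.2.

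Embryos with similar genotypes had similar methylation. Over all pairs of the 35 embryos and 21564 CpGs of intermediate methylation, the correlation of methylation profiles rose with relatedness at the 1296 variant sites (Pearson r 0.726, Spearman rho 0.520, permutation p = 1e-05 for each, the smallest that the permutations can give, adjusted p = 2e-05 over 4 relations), with r of 0.723 without the 2 embryos with the closest relatives and 0.571 without the 13 pairs related above 0.2. Those pairs, 7 of them of different treatments, may be siblings; the closest, control call male replicate 17 and heat call male replicate 28, had a relatedness of 0.444. Undetected C-to-T variants could account for part of the relation, since r was 0.501 over 12022 CpGs checked more strictly for variants, and the part they hold cannot be told apart. By contrast, pairs of the same treatment were not more alike than pairs of different treatments (permutation p = 0.773). Heat call embryos did not differ detectably more from each other than control call embryos did (permutation p = 0.310). Their mean pair correlation was -0.0266, against -0.0303 in control call embryos, so they were if anything slightly more alike. Both questions stay open at this number of embryos.

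The 5 excluded libraries may rest on few DNA molecules. All 5 of them, against every retained heat call female library, read a higher share of intermediate CpGs as all or none methylated, and at CpGs with at least 30 reads that share was 48.2% ± 15.3 (SD, n = 5) against 3.70% ± 2.39 (SD, n = 8). Low depth at the variant sites is argued against as the source of their few heterozygous calls, since 4 of the 5 lay below every retained library at sites with at least 30 reads. Copies of few starting molecules are consistent with both, and among retained libraries heat call female replicate 48 (31.4%) and control call male replicates 42 (28.1%) and 45 (27.5%) had the highest all-or-none shares. Without these 3 libraries 7 CpGs were called for treatment, all among the 13, 33 for labelled sex, and 11 for the interaction, of which 8 were among the 40.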
